A study of Mus musculus with 6 samples.

How the data were processed

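Livers of 3 male Acsm3 knockout and 3 male control mice of 12 weeks on a normal diet were profiled by RNA sequencing of poly(A)-selected RNA, per the labels. The authors deposited 1 table of FPKM values for all 6 libraries, with 28450 genes by Ensembl identifier, symbol and position. HISAT2 2.0.4, Bowtie2 2.2.6, StringTie 1.3.0 and the build GRCm38 are named in the submitters' processing notes, without the role of each tool. Whether the libraries kept strand and how fragments shared by paralogs were counted are not given in the sources used here. Each column name matched the title of 1 sample. Groups and replicate numbers were taken from the titles, and no column of per-sample values was left out.

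Against GENCODE M21 (GRCm38), 28374 identifiers were found and 27170 had the same chromosome, strand, start and end. The deposited FPKM do not state the sequencing depth. FPKM multiplied by the union exon length of a gene moved in steps, and the total at which most of these steps came to 1 fragment was taken for each mouse. With the totals this implied, 97.9% to 98.1% of values under 20 fragments lay within 0.1 of a whole number. The fragments recovered over all genes summed to 102.85% to 103.36% of these totals, more than the totals allow. These totals are estimates, and they were used for depth and for 1 alternative only.

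FPKM were transformed to log2(FPKM + 1). The 10996 genes with a mean of at least 1 FPKM over the 6 mice were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), knockout minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values measure the spread between 3 animals per group, which eBayes moderates across genes. A permutation test of 3 against 3 cannot go below p = 0.1. The gene lists, the rule for named genes and the alternatives were fixed in advance, except where stated. The 58 lists cover acyl-CoA and lipid metabolism, mitochondrial, hepatocyte, stress, immune and matrix functions and markers of other cell types; 126 genes stand in more than 1 list, 191 listed genes lay below the filter and were not tested, and 16 more are not used here. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over the 45 lists. A list of Xist and Y-linked genes served only as a check and was not tested.

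Named genes were first Acsm3 with its family and neighbours. In each direction they were also the 12 genes of largest absolute log2 fold change among those that passed with groups that did not overlap, leaving out predicted genes (1 passed over in each direction). For each list they were up to 4 members that passed with the largest fold, or the 2 of smallest p where none passed. Some members that met this rule are not reported here by name, and they stay in the counts and tests of their lists. Outside this rule, Fads1, Timd4, Hnf4a, Vsig4, Cyp8b1, Clec4f, Fcna, Fads2, Srebf1, Cyp7a1, Marco and Ppara were chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio and quantile scaling, rescaling to a common sum, limma without trend, with robust empirical Bayes or with array weights, a block for the replicate number, leaving out each mouse, and a minimum 2-fold change. After the data were seen, voom (limma) on the recovered fragments and the removal of each mouse's trend on exon length were added. Fits without 1 mouse have less power, so a call lost there need not rest on the mouse left out.

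The procedure was tested on simulated data for this comparison, with 200 of 10996 genes changed: 44.8% of 1.5-fold, 70.2% of 2-fold and 97% of 4-fold changes were called in the right direction, and 6% of the calls were unchanged genes. These folds were set on FPKM + 1, so for genes of low FPKM the shares overstate what is found of such folds in FPKM. The real data gave 1819 calls, far more than the 200 genes changed here, so the shares found there may differ. Camera called both simulated lists that held changed genes and 0 random lists. The simulated genes were drawn independently of each other. The simulation therefore does not test camera on lists of correlated genes, such as antigen presentation with an estimated correlation of 0.704. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for lengths and figures.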

Results

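Hepatic RNA was sequenced from 6 male mice aged 12 weeks on a normal diet. The 3 Acsm3 knockout mice and the 3 control mice were separate animals, and each gave 1 poly(A)-selected library. The deposited values are FPKM, fragments scaled to gene length and library total. The steps between low FPKM values implied totals of 16300000, 15800000 and 15700000 fragments in controls 1, 2 and 3. The totals implied for knockouts 1, 2 and 3 were 15600000, 15300000 and 16200000 fragments. At these totals a gene of 2 kb at 1 FPKM rests on 30.6 to 32.7 fragments. Of 28450 listed genes, 10996 had a mean of at least 1 FPKM and were tested. Xist was listed at no more than 0.0107 FPKM in any library, and the Y-linked gene Ddx3y lay between 22.3 and 28.3 FPKM. Fold changes are log2 values of FPKM + 1, knockout minus control, given ± the SE moderated by limma, with 3 mice in each group. This scale understates the changes of genes with low FPKM.

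The comparison asks how the liver transcriptome differs when Acsm3, which encodes a mitochondrial medium-chain acyl-CoA synthetase, is disrupted. Acsm3 itself was lower in every knockout liver. It was at 33.2, 34.4 and 32.2 FPKM in controls 1, 2 and 3 and at 0.668, 2.92 and 1.08 FPKM in knockouts 1, 2 and 3. The log2 fold change was -3.84 ± 0.29 (limma, adjusted p = 0.00338). The group means, 33.3 ± 1.13 and 1.56 ± 1.2 FPKM (SD, n = 3), differed 21.4-fold. The gene (ENSMUSG00000030935) lies on the plus strand of chromosome 7 at 119760923 to 119787513 in GRCm38. It shares 18835 bp with the exonuclease gene Eri2 on the minus strand. Whether the libraries kept strand is not given in the sources used here, so the fragments left in the knockouts cannot be assigned to either gene with certainty. Which part of Acsm3 was disrupted is not given there either.

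**Figure D1:**
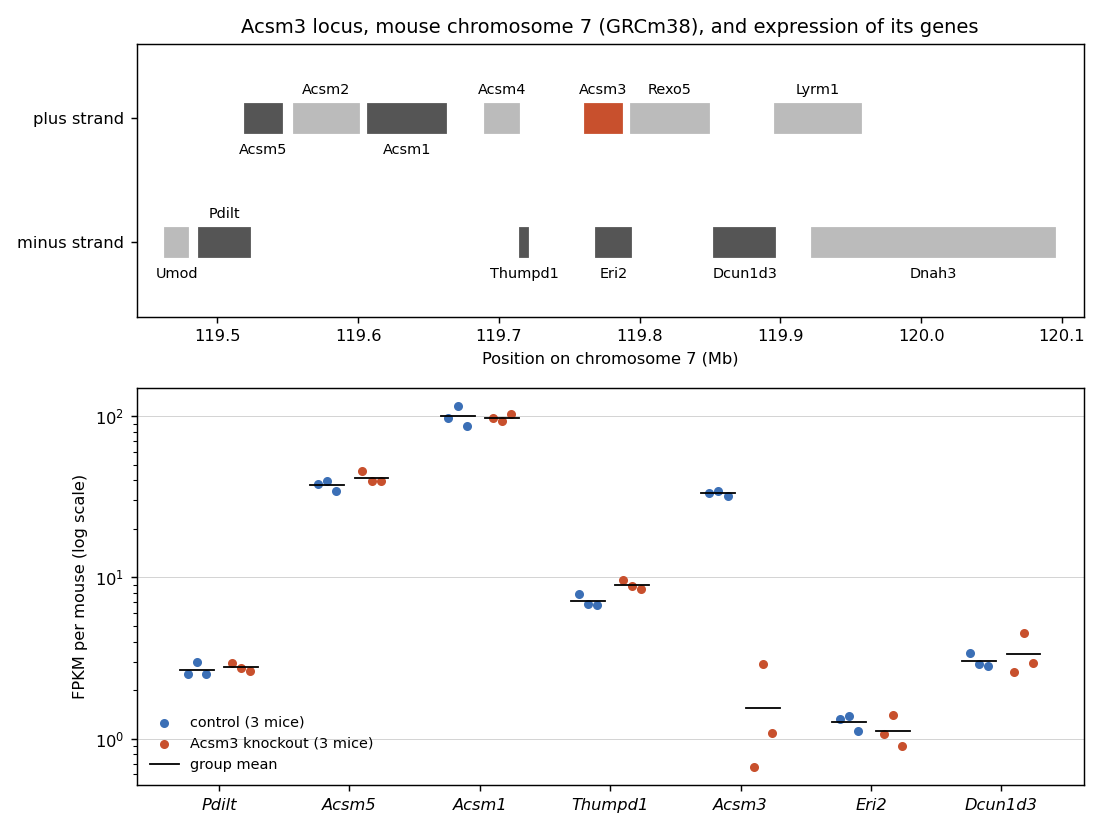
The upper panel maps the protein-coding genes around Acsm3 on chromosome 7 of GRCm38 (position in Mb, strand on the vertical axis), with tested genes dark, genes below the expression filter pale and Acsm3 in orange. The lower panel gives FPKM of the tested genes in each mouse on a log scale with the group means, and Acsm3 lies between 32.2 and 34.4 FPKM in the controls and between 0.668 and 2.92 FPKM in the knockouts.

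Of the Acsm family, whose members lie close together on chromosome 7, Acsm3 was the 1 member that passed among 3 tested (0 higher and 1 lower adjusted over the list alone). Acsm1 was at 99.9 ± 14.6 FPKM in control and 98 ± 4.99 FPKM in knockout livers (SD, n = 3, adjusted p = 0.929 by limma). Acsm5 was at 37.2 ± 2.48 FPKM in control and 41.6 ± 3.58 FPKM in knockout livers (SD, n = 3, adjusted p = 0.266 by limma). Acsm2 and Acsm4 had means of 0.0356 and 0.00493 FPKM over the 6 mice and were not tested. Among 9 tested neighbours of Acsm3, limma called 0 (0 higher and 0 lower adjusted over the list alone), and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.408). The 2 neighbours of smallest p, Thumpd1 and Gde1, were at 0.29 ± 0.09 and -0.22 ± 0.10. Within 10 Mb on either side of Acsm3, 20 of 148 tested genes were called (13.5%), against 1798 of 10847 elsewhere (16.6%, two-sided Fisher's exact test p = 0.373). Of the other acyl-CoA synthetases, 1 of 13 tested genes rose (1 adjusted over the list alone, 0 higher and 0 lower after median-ratio rescaling), namely the arachidonate-preferring Acsl4 (0.46 ± 0.07) (relative median -0.17, camera adjusted p = 0.131). That list was called without knockout 3 (camera adjusted p = 0.0326, 0.0326 to 0.404 over 20 alternatives). Of 4 tested genes of glycine conjugation of acyl-CoAs, limma called 0 (0 higher and 0 lower adjusted over the list alone) and 0 had an unadjusted p under 0.05; Keg1 was at -0.40 ± 0.21. Acsl4 did not pass without control 2 (adjusted p = 0.0561) or knockout 2 (adjusted p = 0.0552). Keg1 passed without knockout 3 (adjusted p = 0.0295). Acsl4 lost its call after median-ratio rescaling (adjusted p = 0.0583).

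Rises and falls were ranked among genes that passed with groups that did not overlap, predicted genes left out. Across the transcriptome, the 12 largest such rises were those of Gstm3 (3.85 ± 0.28), Ly6d (3.71 ± 0.37), Orm3 (3.38 ± 0.32), Gpnmb (3.19 ± 0.34), Scd1 (3.11 ± 0.14), Gsta1 (3.06 ± 0.21), Sult1e1 (3.06 ± 0.26), Col1a1 (2.80 ± 0.31), Col3a1 (2.69 ± 0.23), Cidea (2.65 ± 0.49), Ubd (2.63 ± 0.26) and Mmp12 (2.60 ± 0.34), with adjusted p from 0.000796 to 0.0213. Gstm3 and Gsta1 encode enzymes that conjugate glutathione. Scd1 encodes the main hepatic stearoyl-CoA desaturase, and its FPKM went from 342 ± 64.1 to 2923 ± 188 (SD, n = 3). Beside Acsm3, the 11 largest such falls were those of Acot3 (-2.47 ± 0.22), Cyp17a1 (-2.02 ± 0.22), Hamp2 (-1.87 ± 0.46), Cyp2b9 (-1.58 ± 0.20), Hsd3b5 (-1.50 ± 0.31), Sult2a8 (-1.43 ± 0.26), Cd163 (-1.42 ± 0.33), Cyp4a14 (-1.40 ± 0.23), Raet1d (-1.31 ± 0.24), Sult2a7 (-1.29 ± 0.14) and Mt2 (-1.26 ± 0.14), with adjusted p from 0.00451 to 0.0398. Acot3 encodes a peroxisomal acyl-CoA thioesterase, Cyp17a1 a steroid 17-alpha-hydroxylase and Cyp4a14 a fatty acid omega-hydroxylase. Cd163 encodes the haemoglobin scavenger receptor of macrophages. Gstm3, Ly6d, Orm3, Gpnmb, Scd1, Gsta1, Sult1e1, Col1a1, Col3a1, Ubd, Mmp12, Acot3, Cyp17a1, Cyp2b9, Sult2a7 and Mt2 kept their calls with each mouse left out. Cidea, Hamp2, Hsd3b5, Sult2a8, Cd163, Cyp4a14 and Raet1d did not pass without control 1 (all but Cyp4a14 and Raet1d, adjusted p up to 0.0984), control 2 (all but Cidea, adjusted p up to 0.105), control 3 (all but Cidea, adjusted p up to 0.119), knockout 1 (Cidea and Hsd3b5, adjusted p up to 0.0812), knockout 2 (all but Cyp4a14, adjusted p up to 0.126) or knockout 3 (Hamp2, adjusted p = 0.0764). Gstm3, Gsta1, Orm3, Acot3, Cyp2b9, Cyp4a14, Sult2a7 and Sult2a8 have close paralogs, so how fragments were divided within these families is uncertain.

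**Figure D2:**
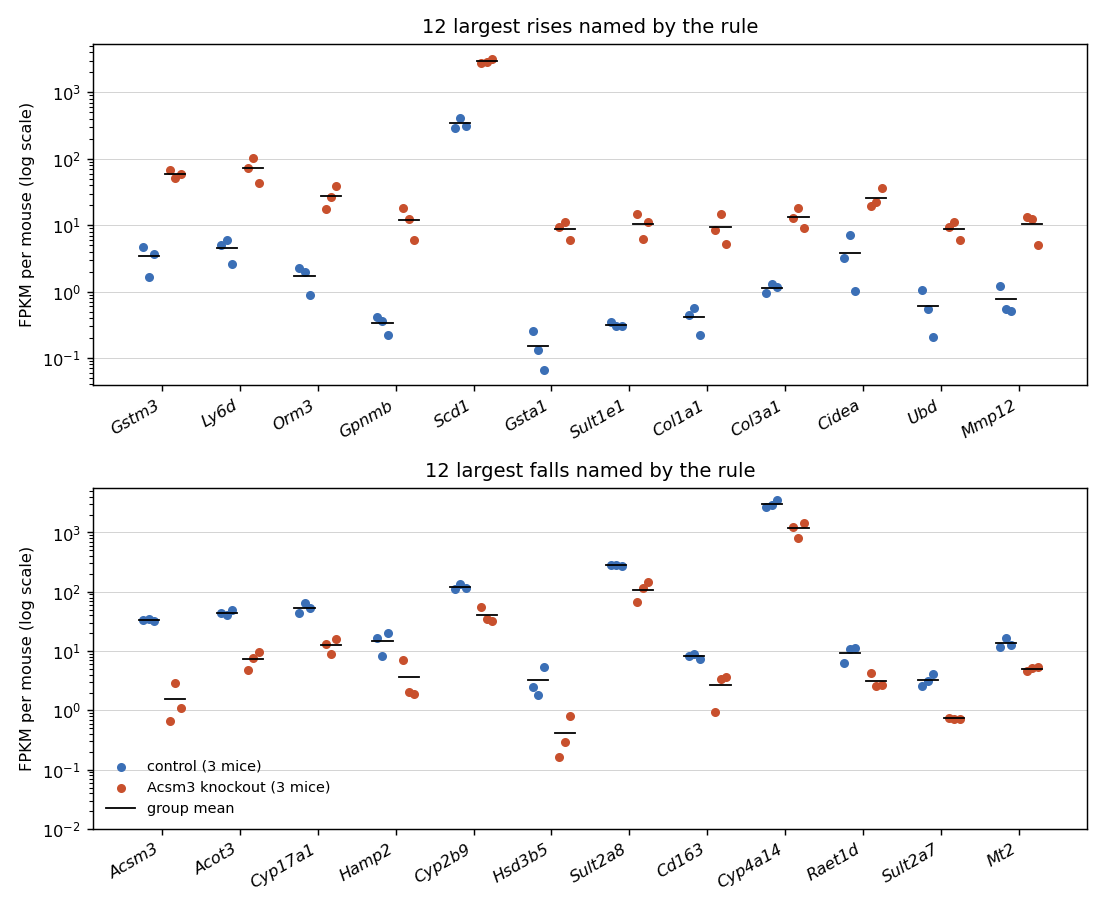
FPKM of the 12 largest rises (upper panel) and 12 largest falls (lower panel) in each mouse, on a log scale, with controls in blue, knockouts in orange and group means as bars. Both are ranked among genes that passed with groups that did not overlap, predicted genes left out. In each gene the 3 knockout values lie on 1 side of the 3 control values, and for Scd1 the means are 342 and 2923 FPKM.

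In all, 1819 genes passed an adjusted p of 0.05 (limma), 1532 of them higher and 287 lower in the knockouts. A change of at least 2-fold was seen in 217 of the higher and 31 of the lower genes. The 3 knockout values lay wholly above or below the 3 control values in 4599 genes (41.8%), where chance gives 10% on average. This count was made on FPKM without rescaling, and genes are not independent. The excess was therefore not shown apart from scaling. The first principal component held 56.1% of the variance and separated the genotypes. Knockout 3, at 10.2, lay nearer to the controls (at most -17.2) than knockouts 1 and 2, at 24.6 and 27.7. The 25 genes of highest mean held 35.7% to 38.4% of summed FPKM in controls and 32.2% to 34% in knockouts. The median log2 fold change of all tested genes was 0.13, and relative medians of lists are given with this value subtracted. The split of calls depended on scaling, with 840 higher and 736 lower after median-ratio rescaling and 752 and 603 after quantile normalization. After rescaling to a common sum, which raised the values, 2582 of 13660 genes past the filter were higher and 238 lower, so that the set tested and the weight of the pseudocount changed with the scaling. None of the named genes that were called under these 3 scalings changed sign. The total also depended on the mice, with 641 genes without control 1, 325 genes without control 2, 287 genes without control 3, 512 genes without knockout 1, 304 genes without knockout 2 and 2250 genes without knockout 3. Lower power with 1 mouse fewer and the weight of single mice were not separated. Of the 287 genes called without control 3, 276 were also called with all mice.

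**Figure D3:**
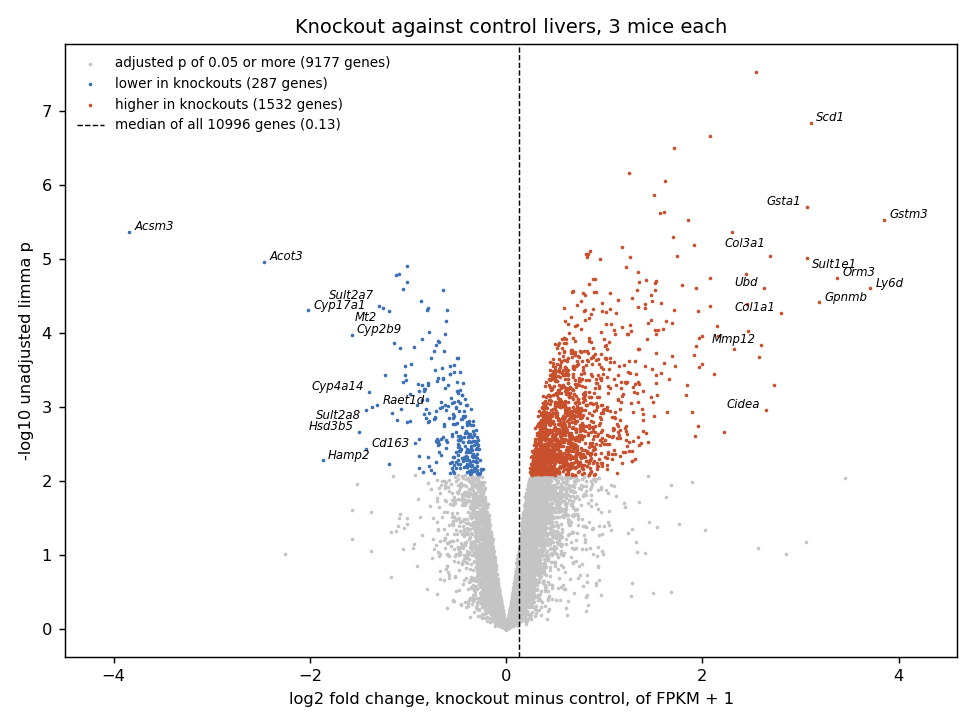
Log2 fold change of FPKM + 1 (horizontal axis, knockout minus control) against the negative log10 of the unadjusted limma p (vertical axis) for 10996 genes. The 1532 higher genes are in orange and the 287 lower genes in blue, and the dashed line marks the median of all genes, 0.13.

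Of 58 gene lists fixed before the data were examined, 45 had at least 5 tested members and were tested as sets. With camera at the preset correlation 29 were called, 11 up and 18 down relative to other genes. With an estimated correlation camera called 0 lists, 9 having an unadjusted p under 0.05. The estimate for the periportal list was 0.011, close to the preset 0.01. Its unadjusted camera p still went from 9.96e-08 with the preset to 0.00613 with the estimate. The loss of calls therefore does not come from correlation between members alone, and the version with an estimate is the stricter test even at like correlation. The rotation test fry, which does not compare a list with other genes, called 18. It kept 15 of the 29 camera calls, lost 14 and gained 3. Where a list has other numbers of higher and lower genes after median-ratio rescaling, they stand beside its counts.

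**Figure D4:**
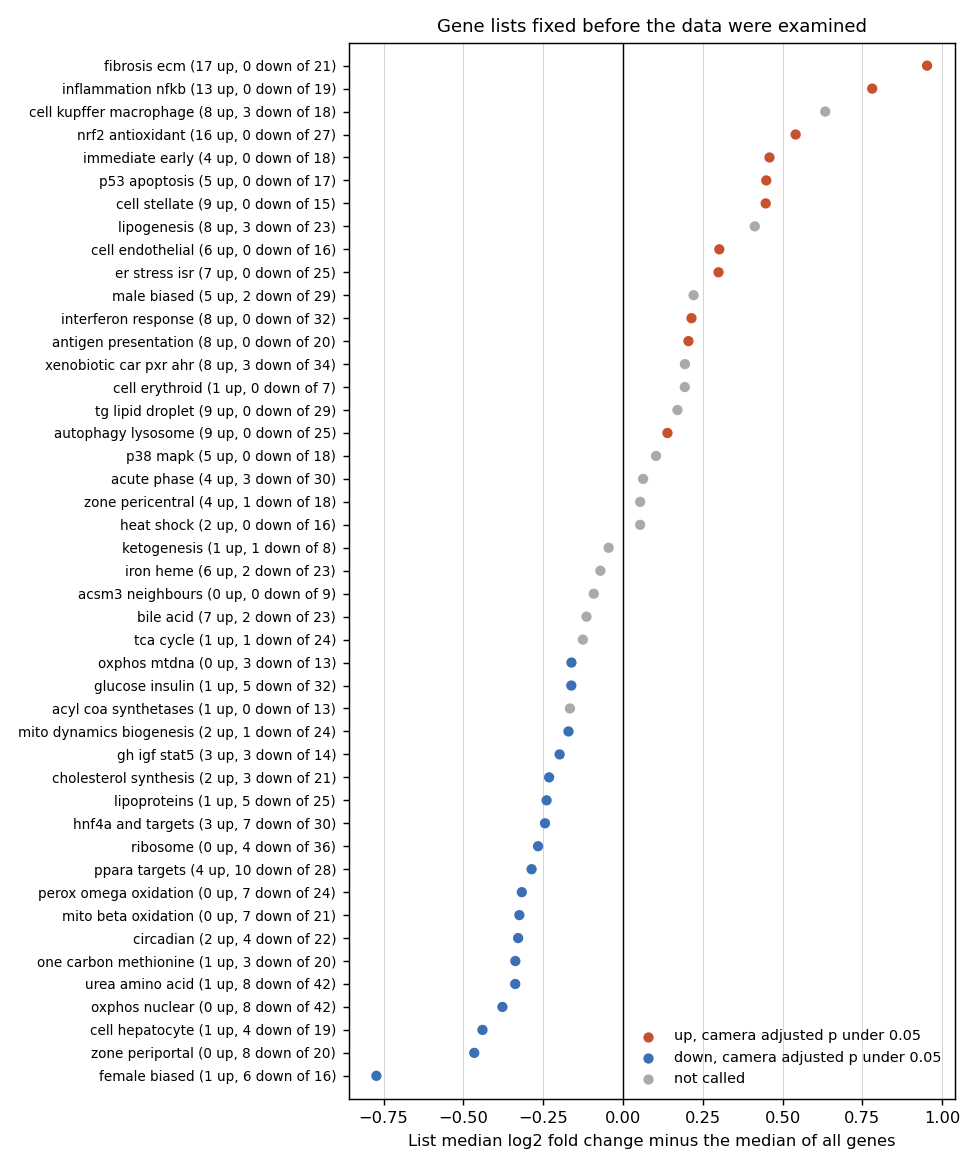
Median log2 fold change of each tested list minus the median of all genes (horizontal axis), with the numbers of members that rose and fell beside each name. Orange and blue mark lists called up and down by camera with the preset correlation, and the values run from -0.77 for female-biased liver genes to 0.95 for matrix genes.

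In the list of fatty acid synthesis, elongation and desaturation, 8 of 23 tested genes rose and 3 fell (11 and 4 adjusted over the list alone, 7 higher and 5 lower after median-ratio rescaling). The rises included Scd1 (3.11 ± 0.14), Fasn (1.42 ± 0.14), Scd2 (1.36 ± 0.18) and Pgd (0.86 ± 0.15), where Fasn encodes fatty acid synthase. The polyunsaturated fatty acid desaturases Fads2 (-0.80 ± 0.09) and Fads1 (-0.53 ± 0.08) fell. Srebf1, which encodes a transcription factor of this pathway, was at -0.03 ± 0.25 (adjusted p = 0.951). The list as a whole was not called by camera (relative median 0.41, camera adjusted p = 0.713) except with quantile normalization (camera adjusted p = 0.0283, 0.0283 to 0.908 over 20 alternatives). Fry called it up (fry adjusted p = 0.0248). Of triglyceride and lipid droplet genes, 9 of 29 tested genes rose (10 adjusted over the list alone, 8 higher and 0 lower after median-ratio rescaling). They included the droplet proteins Cidea (2.65 ± 0.49) and Cidec (2.15 ± 0.26), lipoprotein lipase Lpl (2.32 ± 0.31) and the acyltransferase Mogat1 (1.13 ± 0.23). This list was not called by camera (relative median 0.17, camera adjusted p = 0.0766), but passed with no filter, quantile normalization, array weights or the length trend removed, and without knockout 1 (camera adjusted p = 0.0165, 0.000826 to 0.187 over 20 alternatives). The droplet list was called up by fry (fry adjusted p = 0.041). Of adipocyte markers, 3 of 4 tested genes rose (3 adjusted over the list alone), namely Cidea, Cfd (2.58 ± 0.36) and Fabp4 (1.05 ± 0.16). The other 4 listed adipocyte markers, Adipoq, Plin1, Retn and Lep, had means of 0.0228, 0.00931, 0.0134 and 0.00304 FPKM over the 6 mice and were not tested. Scd1, Fasn, Scd2, Fads2, Cidec, Lpl and Cfd kept their calls with each mouse left out. Pgd, Fads1, Cidea, Mogat1 and Fabp4 did not pass without control 1 (all but Fads1 and Fabp4, adjusted p up to 0.0561), control 2 (Mogat1 and Fabp4, adjusted p up to 0.0565), control 3 (all but Cidea, adjusted p up to 0.0647), knockout 1 (all but Fads1 and Fabp4, adjusted p up to 0.0574) or knockout 2 (all but Fabp4, adjusted p up to 0.0831).

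In the list of cholesterol synthesis, 2 of 21 tested genes rose and 3 fell (2 and 3 adjusted over the list alone, 0 higher and 5 lower after median-ratio rescaling). The cholesterol carrier Stard4 (-0.98 ± 0.17) and squalene synthase Fdft1 (-0.72 ± 0.11) were among the falls, and Hmgcs1 (0.38 ± 0.09) was among the rises. Cholesterol synthesis genes lay below other genes (relative median -0.23, camera adjusted p = 5.37e-05, adjusted p = 0.227 with an estimated correlation). Of lipoprotein genes, 1 of 25 tested genes rose and 5 fell (2 and 6 adjusted over the list alone, 1 higher and 6 lower after median-ratio rescaling). The cholesterol exporter Abca1 (0.70 ± 0.13) rose, and Apoa5 (-0.66 ± 0.16), Apoc4 (-0.46 ± 0.10) and Apom (-0.44 ± 0.07) fell. Lipoprotein genes lay below other genes (relative median -0.24, camera adjusted p = 0.000246, adjusted p = 0.227 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.291, 2.99e-05 to 0.291 over 20 alternatives). Stard4, Fdft1, Hmgcs1, Abca1, Apoa5, Apoc4 and Apom did not pass without control 1 (all but Fdft1, Hmgcs1 and Apom, adjusted p up to 0.082), control 2 (all but Apoa5 and Apom, adjusted p up to 0.119), control 3 (all but Fdft1, adjusted p up to 0.114), knockout 1 (all but Fdft1 and Apom, adjusted p up to 0.0885), knockout 2 (all, adjusted p up to 0.129) or knockout 3 (Hmgcs1 and Apoa5, adjusted p up to 0.0543). Hmgcs1 lost its call after median-ratio rescaling (adjusted p = 0.117) and with quantile normalization (adjusted p = 0.0809).

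Several genes of fatty acid oxidation fell. In mitochondrial beta-oxidation, 7 of 21 tested genes fell (9 adjusted over the list alone, 0 higher and 12 lower after median-ratio rescaling), including the thiolase Acaa2 (-0.38 ± 0.08) and the trifunctional protein subunits Hadha (-0.33 ± 0.07) and Hadhb (-0.33 ± 0.08). Beta-oxidation genes lay below other genes (relative median -0.32, camera adjusted p = 4.3e-10, adjusted p = 0.227 with an estimated correlation), where hepatocyte markers had a relative median of -0.44. In peroxisomal beta-oxidation and omega-oxidation, 7 of 24 tested genes fell (8 adjusted over the list alone, 0 higher and 9 lower after median-ratio rescaling), including Acot3 (-2.47 ± 0.22), Cyp4a14 (-1.40 ± 0.23), Acot4 (-0.97 ± 0.14) and Cyp4a31 (-0.85 ± 0.14). These genes lay below other genes (relative median -0.32, camera adjusted p = 7.13e-07, adjusted p = 0.231 with an estimated correlation). Among targets of the nuclear receptor PPAR-alpha, 4 of 28 tested genes rose and 10 fell (5 and 11 adjusted over the list alone, 4 higher and 11 lower after median-ratio rescaling). Liver fatty acid binding protein, Fabp1 (-1.09 ± 0.10), fell, and Cidec (2.15 ± 0.26) and Fabp4 (1.05 ± 0.16), which are also adipocyte genes, rose. PPAR-alpha targets lay below other genes (relative median -0.29, camera adjusted p = 6.64e-06, adjusted p = 0.231 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.125, 8.13e-07 to 0.125 over 20 alternatives). Ppara itself was at -0.29 ± 0.17 (adjusted p = 0.257). Of ketone body genes, 1 of 8 tested genes rose and 1 fell (1 and 2 adjusted over the list alone, 1 higher and 3 lower after median-ratio rescaling). The monocarboxylate transporter Slc16a1 (0.68 ± 0.11) rose (relative median -0.05, camera adjusted p = 0.303). Acot3, Fabp1 and Cidec kept their calls with each mouse left out. Acaa2, Hadha, Hadhb, Cyp4a14, Acot4, Cyp4a31, Fabp4 and Slc16a1 did not pass without control 1 (Acaa2 and Hadhb, adjusted p up to 0.0564), control 2 (all but Acot4, adjusted p up to 0.131), control 3 (all, adjusted p up to 0.123), knockout 1 (Acaa2, Hadha and Hadhb, adjusted p up to 0.124) or knockout 2 (all but Cyp4a14, Acot4 and Fabp4, adjusted p up to 0.136). Acaa2, Hadha and Hadhb lost their calls with quantile normalization (adjusted p from 0.0522 to 0.0717).

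Some nuclear genes of the respiratory chain fell. In this list 8 of 42 tested genes fell (15 adjusted over the list alone, 0 higher and 22 lower after median-ratio rescaling), with Cox7b (-0.60 ± 0.11), Sdhd (-0.50 ± 0.07), Uqcrb (-0.49 ± 0.12) and Ndufb10 (-0.48 ± 0.11) among the falls. Respiratory chain genes lay below other genes (relative median -0.38, camera adjusted p = 7.1e-16, adjusted p = 0.303 with an estimated correlation). Of cytosolic ribosomal protein genes, 4 of 36 tested genes fell (4 adjusted over the list alone, 0 higher and 14 lower after median-ratio rescaling), among them Rps28 (-0.64 ± 0.13) and Rpl35 (-0.42 ± 0.10). Ribosomal protein genes lay below other genes (relative median -0.27, camera adjusted p = 1.09e-11, adjusted p = 0.231 with an estimated correlation). Of mitochondrially encoded protein genes, 3 of 13 tested genes fell (3 adjusted over the list alone), namely mt-Nd1 (-0.62 ± 0.11), mt-Nd3 (-0.54 ± 0.13) and mt-Nd2 (-0.44 ± 0.11). They lay below other genes (relative median -0.16, camera adjusted p = 0.00106, adjusted p = 0.407 with an estimated correlation). That list lay in the other direction, uncalled, with quantile normalization (camera adjusted p = 0.975, 9.64e-06 to 0.975 over 20 alternatives), and its call ended with the length trend removed. With quantile normalization mt-Nd2 was at -0.04. In the tricarboxylic acid cycle, 1 of 24 tested genes rose and 1 fell (1 and 1 adjusted over the list alone). Citrate synthase Cs (0.62 ± 0.09) rose and fumarase Fh1 (-0.49 ± 0.11) fell (relative median -0.13, camera adjusted p = 0.0727). The cycle's list was called down after median-ratio rescaling, with the length trend removed, and without knockout 3 (camera adjusted p = 0.0168, 0.00667 to 0.561 over 20 alternatives). In mitochondrial biogenesis, dynamics and mitophagy, 2 of 24 tested genes rose and 1 fell (2 and 1 adjusted over the list alone, 0 higher and 3 lower after median-ratio rescaling). The receptor Esrra (-0.54 ± 0.09) fell, and Fundc1 (0.35 ± 0.07) and Mfn2 (0.30 ± 0.07) rose. Genes of this list lay below other genes (relative median -0.17, camera adjusted p = 0.00886, adjusted p = 0.407 with an estimated correlation). Sdhd and Cs kept their calls with each mouse left out. Cox7b, Uqcrb, Ndufb10, Rps28, Rpl35, mt-Nd1, mt-Nd3, mt-Nd2, Fh1, Esrra, Fundc1 and Mfn2 did not pass without control 1 (all but Cox7b, adjusted p up to 0.094), control 2 (all but Rps28, adjusted p up to 0.108), control 3 (all but Cox7b, adjusted p up to 0.115), knockout 1 (all but Cox7b and Esrra, adjusted p up to 0.124), knockout 2 (all, adjusted p up to 0.136) or knockout 3 (Rpl35 and Mfn2, adjusted p up to 0.0631). Fundc1 and Mfn2 lost their calls after median-ratio rescaling (adjusted p from 0.0854 to 0.255). mt-Nd2, Fh1, Fundc1 and Mfn2 lost their calls with quantile normalization (adjusted p from 0.0511 to 0.824).

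Several hepatocyte transcripts fell. Albumin, Alb (-0.61 ± 0.13), took 7.63% to 9.69% of summed FPKM in controls and 5.79% to 6.39% in knockouts. Of hepatocyte markers, 1 of 19 tested genes rose and 4 fell (1 and 7 adjusted over the list alone, 0 higher and 5 lower after median-ratio rescaling), the falls being those of Alb, Arg1 (-0.45 ± 0.09), Ttr (-0.43 ± 0.09) and Hpd (-0.40 ± 0.11). Hepatocyte markers lay below other genes (relative median -0.44, camera adjusted p = 1.61e-09, adjusted p = 0.231 with an estimated correlation). In the urea cycle and amino acid breakdown, 1 of 42 tested genes rose and 8 fell (1 and 8 adjusted over the list alone, 1 higher and 12 lower after median-ratio rescaling), with the transaminases Got1 (-1.11 ± 0.22) and Agxt (-1.07 ± 0.20) among the falls. Urea cycle and amino acid genes lay below other genes (relative median -0.34, camera adjusted p = 1.22e-09, adjusted p = 0.231 with an estimated correlation). In one-carbon and methionine metabolism, 1 of 20 tested genes rose and 3 fell (1 and 6 adjusted over the list alone, 0 higher and 6 lower after median-ratio rescaling). The falls included Ahcy (-0.58 ± 0.11) and Mthfd1 (-0.32 ± 0.08). One-carbon genes lay below other genes (relative median -0.34, camera adjusted p = 1.49e-05, adjusted p = 0.255 with an estimated correlation). Of periportal genes, 8 of 20 tested genes fell (1 higher and 9 lower adjusted over the list alone, 0 higher and 9 lower after median-ratio rescaling), including Etnppl (-0.79 ± 0.16) and Sds (-0.66 ± 0.14). Periportal genes lay below other genes (relative median -0.47, camera adjusted p = 4.98e-07, adjusted p = 0.227 with an estimated correlation). Of pericentral genes, 4 of 18 tested genes rose and 1 fell (5 and 1 adjusted over the list alone, 2 higher and 1 lower after median-ratio rescaling). Ang (-0.89 ± 0.15) fell, and Slc1a4 (0.75 ± 0.18) and glutamine synthetase Glul (0.55 ± 0.09) rose (relative median 0.05, camera adjusted p = 0.823). Alb, Arg1, Ttr, Hpd, Got1, Agxt, Ahcy, Mthfd1, Etnppl, Sds, Ang, Slc1a4 and Glul did not pass without control 1 (all but Got1, Ang and Glul, adjusted p up to 0.0897), control 2 (all but Agxt, Ahcy and Glul, adjusted p up to 0.107), control 3 (all but Etnppl, adjusted p up to 0.137), knockout 1 (all but Ang, adjusted p up to 0.132), knockout 2 (all but Sds and Ang, adjusted p up to 0.152) or knockout 3 (Sds, adjusted p = 0.0527). Alb, Ttr, Hpd and Slc1a4 lost their calls with quantile normalization (adjusted p from 0.0549 to 1). Alb ranks first in every library, so quantile normalization gives it the same value in all 6.

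Glycogen and gluconeogenesis genes fell in part. In the list of gluconeogenesis, glycolysis and insulin response, 1 of 32 tested genes rose and 5 fell (4 and 8 adjusted over the list alone, 1 higher and 7 lower after median-ratio rescaling). Glycogen synthase Gys2 (-0.94 ± 0.12), the phosphatase subunit Ppp1r3g (-0.93 ± 0.21) and the gluconeogenic enzymes G6pc (-0.91 ± 0.16) and Pck1 (-0.79 ± 0.20) fell. Glucose-handling genes lay below other genes (relative median -0.16, camera adjusted p = 0.000884, adjusted p = 0.292 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.163, 3.15e-05 to 0.163 over 20 alternatives). Of Hnf4a and its liver targets, 3 of 30 tested genes rose and 7 fell (3 and 8 adjusted over the list alone, 1 higher and 7 lower after median-ratio rescaling). Hnf4a, a transcription factor of hepatocyte identity, was itself higher at 0.70 ± 0.12. Cyp3a11 (1.51 ± 0.10) rose and Slc10a1 (-1.19 ± 0.13) fell. Hnf4a targets lay below other genes (relative median -0.24, camera adjusted p = 0.000394, adjusted p = 0.231 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.561, 1.53e-05 to 0.561 over 20 alternatives). In bile acid synthesis and transport, 7 of 23 tested genes rose and 2 fell (9 and 3 adjusted over the list alone, 6 higher and 3 lower after median-ratio rescaling). The basolateral uptake transporter Slc10a1 fell, and the efflux transporters Abcc3 (0.98 ± 0.10) and Abcc4 (0.81 ± 0.13) and the hydroxylase Cyp2c70 (1.36 ± 0.31) rose (relative median -0.11, camera adjusted p = 0.445). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.39 ± 0.34 and Cyp8b1 at -0.14 ± 0.31 (adjusted p = 0.447 and 0.774). Gys2, Cyp3a11, Slc10a1 and Abcc3 kept their calls with each mouse left out. Ppp1r3g, G6pc, Pck1, Hnf4a, Abcc4 and Cyp2c70 did not pass without control 1 (Ppp1r3g and Pck1, adjusted p up to 0.0833), control 2 (all, adjusted p up to 0.102), control 3 (all, adjusted p up to 0.119), knockout 1 (all but G6pc and Abcc4, adjusted p up to 0.122), knockout 2 (G6pc, Abcc4 and Cyp2c70, adjusted p up to 0.0767) or knockout 3 (Pck1 and Cyp2c70, adjusted p up to 0.0821). Abcc4 fell below the filter without knockout 1 and was then not tested. Hnf4a lost its call after median-ratio rescaling (adjusted p = 0.0522). Pck1 lost its call with quantile normalization (adjusted p = 0.087).

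Genes that differ between the sexes in mouse liver moved unevenly. Of female-biased genes, 1 of 16 tested genes rose and 6 fell (1 and 10 adjusted over the list alone, 1 higher and 8 lower after median-ratio rescaling). Cyp17a1 (-2.02 ± 0.22), Hamp2 (-1.87 ± 0.46) and Cyp2b9 (-1.58 ± 0.20) fell, while oestrogen sulfotransferase Sult1e1 (3.06 ± 0.26) rose. Female-biased genes lay below other genes (relative median -0.77, camera adjusted p = 1.01e-07, adjusted p = 0.227 with an estimated correlation). Of male-biased genes, 5 of 29 tested genes rose and 2 fell (5 and 2 adjusted over the list alone). Mup20 (1.93 ± 0.26) and Selenbp2 (1.79 ± 0.17) rose and Hsd3b5 (-1.50 ± 0.31) fell. The relative median of the male-biased genes was 0.22 and their mean log2 fold change 0.48, while camera's direction was down and not called (camera adjusted p = 0.658). Without knockout 3 it was called (camera adjusted p = 0.0418, 0.0418 to 0.987 over 20 alternatives). The Mup genes are close paralogs. In growth hormone, IGF-1 and STAT5 output, 3 of 14 tested genes rose and 3 fell (4 and 5 adjusted over the list alone, 0 higher and 5 lower after median-ratio rescaling). Igfals (-0.81 ± 0.15) and Igf1 (-0.51 ± 0.11) fell and Igfbp3 (0.66 ± 0.14) rose. Genes of this output lay below other genes (relative median -0.20, camera adjusted p = 0.0344, adjusted p = 0.303 with an estimated correlation). The call ended without control 3 or knockout 1 (camera adjusted p = 0.103 and 0.13), after median-ratio or quantile scaling and with a filter at 5 FPKM (0.0117 to 0.482 over 20 alternatives). Cyp17a1, Cyp2b9, Sult1e1, Mup20 and Selenbp2 kept their calls with each mouse left out. Hamp2, Hsd3b5, Igfals, Igf1 and Igfbp3 did not pass without control 1 (all, adjusted p up to 0.0984), control 2 (all, adjusted p up to 0.0833), control 3 (all, adjusted p up to 0.119), knockout 1 (all but Hamp2, adjusted p up to 0.0812), knockout 2 (all but Igfals, adjusted p up to 0.126) or knockout 3 (Hamp2, adjusted p = 0.0764). Igfbp3 lost its call after median-ratio rescaling (adjusted p = 0.0685) and with quantile normalization (adjusted p = 0.0746).

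Most antioxidant and glutathione genes rose. Of NRF2 targets and antioxidant enzymes, 16 of 27 tested genes rose (20 higher and 1 lower adjusted over the list alone, 15 higher and 1 lower after median-ratio rescaling). The rises included Gstm3 (3.85 ± 0.28), Gsta1 (3.06 ± 0.21), Gsta2 (2.22 ± 0.46) and Gstm2 (1.61 ± 0.11) and haem oxygenase 1, Hmox1 (1.34 ± 0.12). NRF2 and antioxidant genes lay above other genes (relative median 0.54, camera adjusted p = 2.83e-07, adjusted p = 0.357 with an estimated correlation). The Gsta and Gstm genes are close paralogs. Of genes under the receptors CAR, PXR and AhR, 8 of 34 tested genes rose and 3 fell (10 and 4 adjusted over the list alone, 5 higher and 3 lower after median-ratio rescaling). Ces2c (1.97 ± 0.25) and Cyp3a11 (1.51 ± 0.10) rose and Cyp2b9 (-1.58 ± 0.20) fell (relative median 0.19, camera adjusted p = 0.778). That list was called with quantile normalization (camera adjusted p = 0.0161, 0.0161 to 0.906 over 20 alternatives). Of iron and haem genes, 6 of 23 tested genes rose and 2 fell (6 and 4 adjusted over the list alone, 3 higher and 5 lower after median-ratio rescaling). Hmox1, Cp (0.78 ± 0.12) and Slc11a2 (0.64 ± 0.11) rose and Hamp2 (-1.87 ± 0.46) fell (relative median -0.07, camera adjusted p = 0.297). Gstm3, Gsta1, Gstm2, Hmox1, Ces2c, Cyp3a11 and Cyp2b9 kept their calls with each mouse left out. Gsta2, Cp, Slc11a2 and Hamp2 did not pass without control 1 (Slc11a2 and Hamp2, adjusted p up to 0.0984), control 2 (all but Cp, adjusted p up to 0.0639), control 3 (all, adjusted p up to 0.119), knockout 1 (Gsta2, adjusted p = 0.082), knockout 2 (all, adjusted p up to 0.126) or knockout 3 (Hamp2, adjusted p = 0.0764).

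Extracellular matrix genes had the highest relative median of the tested lists. In matrix and fibrogenesis, 17 of 21 tested genes rose (17 adjusted over the list alone). The rises included the collagens Col1a1 (2.80 ± 0.31), Col3a1 (2.69 ± 0.23) and Col1a2 (2.08 ± 0.20) and the collagenase Mmp13 (1.71 ± 0.19). Col1a1 was at 0.41 ± 0.171 FPKM in control and 9.47 ± 4.82 FPKM in knockout livers (SD, n = 3). Matrix genes lay above other genes (relative median 0.95, camera adjusted p = 3.87e-08, adjusted p = 0.357 with an estimated correlation). Of stellate cell and fibroblast markers, 9 of 15 tested genes rose (12 adjusted over the list alone, 7 higher and 0 lower after median-ratio rescaling), among them Dpt (1.52 ± 0.19), Lum (1.47 ± 0.17) and Dcn (0.70 ± 0.09). Stellate markers lay above other genes (relative median 0.45, camera adjusted p = 0.000117, adjusted p = 0.357 with an estimated correlation). Of liver endothelial markers, 6 of 16 tested genes rose (10 adjusted over the list alone, 3 higher and 0 lower after median-ratio rescaling), such as Stab1 (0.74 ± 0.13) and Stab2 (0.67 ± 0.14). Endothelial markers lay above other genes (relative median 0.30, camera adjusted p = 0.01, adjusted p = 0.565 with an estimated correlation). Of cholangiocyte markers, 2 of 4 tested genes rose (2 adjusted over the list alone), namely Spp1 (1.61 ± 0.23) and Tm4sf4 (0.87 ± 0.13). The others of the 14 listed lay below the filter and were not tested. Among them were Krt19, Krt7, Epcam and Sox9, with means of 0.359, 0.0522, 0.684 and 0.735 FPKM over all mice. Of mesothelial markers, 2 of 3 tested genes rose (3 adjusted over the list alone), namely Krt8 (1.29 ± 0.21) and Krt18 (0.94 ± 0.15), keratins that hepatocytes also express. Hepatocyte markers had a relative median of -0.44 in the same libraries. Col1a1, Col3a1, Col1a2, Dpt, Lum and Dcn kept their calls with each mouse left out. Stab1, Stab2, Spp1, Tm4sf4, Krt8 and Krt18 did not pass without control 1 (Stab1 and Stab2, adjusted p up to 0.07), control 2 (Stab1, Stab2 and Krt8, adjusted p up to 0.0778), control 3 (all, adjusted p up to 0.0807), knockout 1 (all but Spp1 and Tm4sf4, adjusted p up to 0.0601) or knockout 2 (all but Spp1 and Krt8, adjusted p up to 0.0897). Mmp13 fell below the filter without knockout 1 and was then not tested.

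Many inflammatory and antigen-presentation genes rose. Of cytokine, chemokine and NF-kB genes, 13 of 19 tested genes rose (15 higher and 1 lower adjusted over the list alone, 11 higher and 0 lower after median-ratio rescaling). The rises included the chemokines Ccl2 (1.94 ± 0.19), Cxcl1 (1.72 ± 0.25) and Cxcl10 (1.23 ± 0.19) and the receptor Tlr2 (1.14 ± 0.17). Inflammatory genes lay above other genes (relative median 0.78, camera adjusted p = 0.000394, adjusted p = 0.407 with an estimated correlation). Of MHC and antigen-presentation genes, 8 of 20 tested genes rose (10 adjusted over the list alone, 8 higher and 1 lower after median-ratio rescaling), with the class II genes H2-Eb1 (2.16 ± 0.27) and H2-Ab1 (1.96 ± 0.40) and the invariant chain Cd74 (1.91 ± 0.26). In knockouts 1, 2 and 3, H2-Ab1 was at 67.4, 57.1 and 21.9 FPKM and Cd74 at 180.2, 186 and 91 FPKM, and knockout 3 also had the lowest mean of macrophage markers among the knockouts. Antigen-presentation genes lay above other genes (relative median 0.20, camera adjusted p = 0.0031, adjusted p = 0.596 with an estimated correlation). Of interferon-stimulated genes, 8 of 32 tested genes rose (12 adjusted over the list alone), among them Gbp2 (1.18 ± 0.14), Oas1a (0.88 ± 0.18), Ifit2 (0.88 ± 0.20) and Rsad2 (0.80 ± 0.14). Interferon-stimulated genes lay above other genes (relative median 0.21, camera adjusted p = 0.00389, adjusted p = 0.638 with an estimated correlation). Of acute-phase genes, 4 of 30 tested genes rose and 3 fell (5 and 4 adjusted over the list alone, 4 higher and 4 lower after median-ratio rescaling). Orm3 (3.38 ± 0.32), Orm2 (1.90 ± 0.35) and Steap4 (1.35 ± 0.18) rose and Mt2 (-1.26 ± 0.14) fell. The relative median of the acute-phase genes was 0.06 and their mean log2 fold change 0.30, while camera's direction was down and not called (camera adjusted p = 0.194). It was called with array weights and without control 1 (camera adjusted p = 0.0146, 0.0146 to 0.947 over 20 alternatives). Ccl2, Cxcl1, H2-Eb1, Cd74, Gbp2, Orm3, Steap4 and Mt2 kept their calls with each mouse left out. Cxcl10, Tlr2, H2-Ab1, Oas1a, Ifit2, Rsad2 and Orm2 did not pass without control 1 (all but Cxcl10, Tlr2 and Rsad2, adjusted p up to 0.0872), control 2 (all but Orm2, adjusted p up to 0.0813), control 3 (all but Tlr2 and Orm2, adjusted p up to 0.103), knockout 1 (all but Cxcl10, Tlr2 and Rsad2, adjusted p up to 0.0979) or knockout 2 (all but Cxcl10, adjusted p up to 0.112).

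Macrophage markers moved in both directions. Of this list 8 of 18 tested genes rose and 3 fell (10 and 4 adjusted over the list alone, 6 higher and 4 lower after median-ratio rescaling). The mean log2(FPKM + 1) of its tested genes was 4.49 and 4.72 in knockouts 1 and 2, and 4.05 in knockout 3, within the 3.72 to 4.18 of the controls. The cathepsin Ctss (1.40 ± 0.23), the lysosomal marker Cd68 (1.35 ± 0.29) and lysozyme Lyz2 (1.28 ± 0.32) rose. Cd163 (-1.42 ± 0.33), Timd4 (-0.81 ± 0.14) and Fcna (-0.81 ± 0.14), genes known from resident macrophages, fell. The Kupffer cell genes Clec4f and Vsig4 were at 0.39 ± 0.23 and 0.51 ± 0.23 and Marco at -1.52 ± 0.44 (adjusted p = 0.272, 0.157 and 0.0586). The macrophage list was not called (relative median 0.63, camera adjusted p = 0.463) except after median-ratio or quantile scaling (camera adjusted p = 0.0431 and 0.0134, 0.0134 to 0.948 over 20 alternatives). Ctss, Cd68, Lyz2, Cd163, Timd4 and Fcna did not pass without control 1 (all but Ctss, adjusted p up to 0.0833), control 2 (all, adjusted p up to 0.105), control 3 (all but Timd4 and Fcna, adjusted p up to 0.107), knockout 1 (all but Cd163, adjusted p up to 0.113) or knockout 2 (all but Fcna, adjusted p up to 0.128). Marco passed without control 3 (adjusted p = 0.0464). Vsig4 passed without knockout 3 (adjusted p = 0.0174). Marco passed after median-ratio rescaling (adjusted p = 0.0486). Marco passed with quantile normalization (adjusted p = 0.0447).

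Of neutrophil markers, 3 of 4 tested genes rose (3 adjusted over the list alone), such as Retnlg (1.22 ± 0.25) and S100a8 (0.79 ± 0.17). The others of the 12 listed had means of 0 to 0.261 FPKM over the 6 mice and were not tested. Retnlg was at 0.172 FPKM in control and 1.83 FPKM in knockout livers, and S100a8 at 0.48 and 1.57 FPKM. Both thus passed the filter through their knockout values. The mean log2(FPKM + 1) of the tested neutrophil markers was 1.83, 1.73 and 1.04 in knockouts 1, 2 and 3. The single T and NK cell marker tested, Ccl5 (0.94 ± 0.24), rose (1 higher and 0 lower adjusted over the list alone, 0 higher and 0 lower after median-ratio rescaling). Of red blood cell markers, 1 of 7 tested genes rose (1 adjusted over the list alone, 0 higher and 0 lower after median-ratio rescaling), namely Alas2 (0.59 ± 0.15) (relative median 0.19, camera adjusted p = 0.566). Of 3 tested B cell and plasma cell markers, limma called 0 (0 higher and 0 lower adjusted over the list alone) and 0 had an unadjusted p under 0.05, with Ighm at 0.83 ± 1.08. Ighm was at 4.02, 121 and 14.1 FPKM in knockouts 1, 2 and 3, with knockout 2 far apart. Controls 1, 2 and 3 were at 8.99, 19.6 and 7.02 FPKM. The platelet marker Pf4 was at 0.81 ± 0.25 (adjusted p = 0.0705, 1 higher and 0 lower adjusted over the list alone). The pancreas marker Cela1 was at -0.30 ± 0.14 (adjusted p = 0.184, 0 higher and 0 lower adjusted over the list alone). The muscle markers Myl9 and Des were at 0.36 ± 0.13 and 0.32 ± 0.12 (adjusted p = 0.102 and 0.105, 2 higher and 0 lower adjusted over the list alone). Retnlg, S100a8, Ccl5 and Alas2 did not pass without control 1 (all, adjusted p up to 0.0689), control 2 (all, adjusted p up to 0.122), control 3 (all, adjusted p up to 0.117), knockout 1 (Ccl5, adjusted p = 0.12), knockout 2 (Ccl5 and Alas2, adjusted p up to 0.134) or knockout 3 (Alas2, adjusted p = 0.0742). Retnlg and S100a8 fell below the filter without knockout 1 and were then not tested. Retnlg, S100a8 and Pf4 fell below the filter without knockout 2 and were then not tested. Des passed without knockout 3 (adjusted p = 0.0374). Ccl5 and Alas2 lost their calls after median-ratio rescaling (adjusted p from 0.0507 to 0.124) and with quantile normalization (adjusted p from 0.0674 to 0.072). Cela1 passed with quantile normalization (adjusted p = 0.0351).

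Some stress-kinase and immediate-early genes rose. In the p38 MAPK cascade, 5 of 18 tested genes rose (7 adjusted over the list alone, 3 higher and 0 lower after median-ratio rescaling). Mapk14, which encodes p38-alpha, went from 16.2 ± 0.841 to 29.9 ± 0.966 FPKM (SD, n = 3). Mapk14 (0.85 ± 0.07), Ddit3 (0.85 ± 0.21) and Map3k5 (0.69 ± 0.12) were among the rises (relative median 0.10, camera adjusted p = 0.15). The p38 list was called with no filter (camera adjusted p = 0.0101, 0.0101 to 0.295 over 20 alternatives) and by fry (fry adjusted p = 0.0248). Of immediate-early genes, 4 of 18 tested genes rose (7 adjusted over the list alone), namely Klf6 (1.69 ± 0.20), Atf3 (1.58 ± 0.24), Zfp36 (1.53 ± 0.15) and Myc (1.18 ± 0.10). Immediate-early genes lay above other genes (relative median 0.46, camera adjusted p = 0.0273, adjusted p = 0.637 with an estimated correlation). That call ended with a filter at 5 FPKM and without control 2, knockout 1 or knockout 2 (camera adjusted p = 0.0603, 0.0764 and 0.0998, 0.00018 to 0.19 over 20 alternatives). Mapk14, Klf6, Zfp36 and Myc kept their calls with each mouse left out. Ddit3, Map3k5 and Atf3 did not pass without control 1 (Ddit3 and Map3k5, adjusted p up to 0.0551), control 2 (Ddit3 and Atf3, adjusted p up to 0.0963), control 3 (all, adjusted p up to 0.0913), knockout 1 (Ddit3 and Map3k5, adjusted p up to 0.11), knockout 2 (Ddit3 and Map3k5, adjusted p up to 0.0653) or knockout 3 (Ddit3, adjusted p = 0.076). Ddit3 lost its call after median-ratio rescaling (adjusted p = 0.0581) and with quantile normalization (adjusted p = 0.073).

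Genes of protein folding stress and p53 output also rose in part. In the unfolded protein and integrated stress response, 7 of 25 tested genes rose (10 adjusted over the list alone, 3 higher and 0 lower after median-ratio rescaling), including Manf (0.98 ± 0.18) and Creld2 (0.80 ± 0.19). Genes of this response lay above other genes (relative median 0.30, camera adjusted p = 0.00585, adjusted p = 0.407 with an estimated correlation). Of heat shock genes, 2 of 16 tested genes rose (2 adjusted over the list alone, 1 higher and 1 lower after median-ratio rescaling), namely Hspb1 (1.27 ± 0.19) and Hspa4l (0.55 ± 0.10) (relative median 0.05, camera adjusted p = 0.718). Of p53 targets and apoptosis genes, 5 of 17 tested genes rose (7 adjusted over the list alone), among them Cdkn1a (1.92 ± 0.41) and Mdm2 (0.73 ± 0.13). p53 and apoptosis genes lay above other genes (relative median 0.45, camera adjusted p = 0.0161, adjusted p = 0.536 with an estimated correlation). Of cell cycle genes, 2 of 4 tested genes rose (3 adjusted over the list alone, 1 higher and 0 lower after median-ratio rescaling), namely Ccnd1 (1.11 ± 0.27) and Mcm3 (0.43 ± 0.10). Of autophagy and lysosome genes, 9 of 25 tested genes rose (14 adjusted over the list alone, 3 higher and 0 lower after median-ratio rescaling), among them Sqstm1 (0.90 ± 0.17) and Ctsd (0.75 ± 0.12). Autophagy and lysosome genes lay above other genes (relative median 0.14, camera adjusted p = 0.0236, adjusted p = 0.565 with an estimated correlation), a call that ended after median-ratio rescaling (camera adjusted p = 0.054, 0.000769 to 0.054 over 20 alternatives). Manf, Creld2, Hspb1, Hspa4l, Cdkn1a, Mdm2, Ccnd1, Mcm3, Sqstm1 and Ctsd did not pass without control 1 (Manf, Creld2, Hspa4l, Cdkn1a and Mcm3, adjusted p up to 0.098), control 2 (all but Manf, adjusted p up to 0.105), control 3 (all but Hspb1, adjusted p up to 0.113), knockout 1 (Hspa4l, Cdkn1a, Mdm2, Ccnd1 and Mcm3, adjusted p up to 0.103) or knockout 2 (all but Hspb1 and Hspa4l, adjusted p up to 0.127). Creld2, Hspa4l and Mcm3 lost their calls after median-ratio rescaling (adjusted p from 0.0515 to 0.0905) and with quantile normalization (adjusted p from 0.0871 to 0.165).

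Some clock and clock-output genes fell. In this list 2 of 22 tested genes rose and 4 fell (2 and 4 adjusted over the list alone). Noct (-1.02 ± 0.16) and Per3 (-0.77 ± 0.11) were among the falls and Tsku (1.23 ± 0.20) was among the rises. Clock genes lay below other genes (relative median -0.33, camera adjusted p = 2.17e-05, adjusted p = 0.263 with an estimated correlation). Per3 kept its call with each mouse left out. Noct and Tsku did not pass without control 2 (Noct and Tsku, adjusted p up to 0.0519), control 3 (Noct and Tsku, adjusted p up to 0.0573) or knockout 2 (Noct and Tsku, adjusted p up to 0.0583).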

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

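The voom and length alternatives were chosen after the data were seen. Acsm3 stayed lower and called under all 20 alternatives, with log2 fold changes of -4.70 to -2.56. The count of 1819 genes (1532 higher, 287 lower) became 650 genes (544 higher, 106 lower) with no filter, where more genes share the adjustment, and 1108 genes (848 higher, 260 lower) with a mean of at least 5 FPKM, where fewer are tested. A 2-fold minimum left 248 genes (217 higher, 31 lower) by construction. Median-ratio rescaling gave 1576 genes (840 higher, 736 lower), and quantile normalization 1355 genes (752 higher, 603 lower), both moving the median of all genes. Rescaling to a common sum gave 2820 genes (2582 higher, 238 lower), with 13660 genes past the filter against 10996 and a smaller weight of the pseudocount, so scaling was not the sole change. Array weights gave 3279 genes (2742 higher, 537 lower), and the cause was not tested. Removing the length trend gave 1640 genes (1409 higher, 231 lower), and together with median-ratio rescaling 1452 genes (833 higher, 619 lower), while voom gave 2134 genes (1816 higher, 318 lower). Leaving out 1 mouse gave 641 genes without control 1, 325 genes without control 2, 287 genes without control 3, 512 genes without knockout 1, 304 genes without knockout 2 and 2250 genes without knockout 3, 226 to 1968 of them higher and 55 to 282 lower, and the cause of the rise without knockout 3 was not tested. Limma without the trend or with robust estimates called 1760 and 1825.

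Of 180 named genes that passed, 163 kept their calls after median-ratio rescaling, 153 with quantile normalization, 95 with no filter and 66 to 167 with 1 mouse left out. Under all alternatives in which they were tested, 56 kept them, and the fits without 1 mouse also have less power. Camera called 29 lists, 28 to 32 with 1 mouse left out and 0 with an estimated correlation (9 at an unadjusted p under 0.05). Fry, which asks another question, called 18, keeping 15 of the 29, losing 14 and gaining 3. The list of mitochondrially encoded proteins changed direction with quantile normalization (camera adjusted p = 0.975, 9.64e-06 to 0.975 over 20 alternatives), and the cause was not tested. With the replicate number as a block, the count was 2018 genes (1672 higher, 346 lower), and 29 lists were called. Deviations of same-numbered mice correlated at 0.111, 0.0918 and 0.187 across genes, which are not independent, and not all over 0.1, so the numbers are not taken as pairs. Each mouse correlated best with its own number, which is a hint from the data and not from the design. At 15300000 to 16300000 fragments, genes under 1 FPKM rest on few fragments and were not tested.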

Other observations

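All tests in this part except that of the splits were chosen after the differences they address were seen, though the limits for the length tests were set before their outcomes. The genes of this paragraph were chosen after their values were seen. Gpnmb rose beside Lgals3 (2.47 ± 0.30), Cd63 (1.97 ± 0.29), Clec7a (1.84 ± 0.30), Itgax (1.49 ± 0.22) and Atp6v0d2 (1.47 ± 0.25), genes known from activated or lipid-laden macrophages (adjusted p from 0.00895 to 0.018). No list of such genes was tested, and the list of macrophage markers was not called (camera adjusted p = 0.463). Knockout 3 had the lowest knockout value of each of these genes, as for Lgals3 at 25.6, 27.6 and 11.7 FPKM and Itgax at 3.54, 3.37 and 1.58 FPKM in knockouts 1, 2 and 3. Trem2, another such gene, was at 0.449 ± 0.219 FPKM in control and 2.65 ± 1.05 FPKM in knockout livers (SD, n = 3) and passed (adjusted p = 0.0216 by limma). The mitochondrial ribosomal RNA genes mt-Rnr1 (-0.86 ± 0.15) and mt-Rnr2 (-1.12 ± 0.10) fell in these poly(A)-selected libraries. How the selection caught ribosomal RNA in each library was not tested. The mitochondrial mRNA genes mt-Cytb and mt-Nd4 were at 0.12 ± 0.11 and 0.01 ± 0.09 (adjusted p = 0.467 and 0.928). The metallothionein Mt1 (-1.24 ± 0.19) fell with Mt2. Lgals3 and mt-Rnr2 kept their calls with each mouse left out. Cd63, Clec7a, Itgax, Atp6v0d2, Trem2, mt-Rnr1 and Mt1 did not pass without control 1 (Atp6v0d2, adjusted p = 0.0534), control 2 (all but Cd63, mt-Rnr1 and Mt1, adjusted p up to 0.0749), control 3 (all, adjusted p up to 0.0708), knockout 1 (Trem2 and mt-Rnr1, adjusted p up to 0.0634) or knockout 2 (all but Cd63, adjusted p up to 0.0771). mt-Cytb passed with quantile normalization (adjusted p = 0.0438).

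Of the 10 splits of the 6 mice into 3 and 3, 1 gave as many genes as the real one, 1819, itself included. The highest of the other splits gave 0 by limma, with up to 933 genes at an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05. Every other split mixes the genotypes within its groups, which adds any genotype difference to the spread within them. Few calls there therefore decide nothing about the real split.

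Far more genes were called higher than lower, 84.2% of calls. After the length trend was removed the share was 85.9%. That removal keeps each mouse's median by design, the median of all genes being 0.13 before and 0.133 after. The share therefore decides nothing about gene length bias. Scaling of FPKM and a general rise per cell in the knockouts cannot be told apart here. The share was 53.3% after median-ratio rescaling, but that rescaling puts the median of all genes near 0 by design and so decides nothing. Respiratory chain and ribosomal transcripts are short, and their lists lay lower. Length as the whole cause is argued against for the respiratory chain list, whose relative median was -0.38 before and -0.32 after removal (SD of members 0.14, camera adjusted p = 1.71e-14). With an estimated correlation that list was not called before removal (camera adjusted p = 0.303), and this was not repeated after it. The ribosomal list had relative medians of -0.27 before and -0.23 after removal, with an SD of members of 0.22. It also kept its call (camera adjusted p = 3.57e-08 after removal, and 0.231 with an estimated correlation before it). A part of length stays open there. Over the tested genes, log2 fold changes correlated with exon length (Spearman 0.186) and with mean log2 expression (Spearman -0.204). Whether mean expression plays a part in the lower lists was not tested.

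Stellate, matrix and some macrophage genes rose while 4 of 19 hepatocyte markers were called lower and 1 higher (camera adjusted p = 1.61e-09, and 0.231 with an estimated correlation), and a lower share of hepatocytes in the tissue may contribute. This was tested first on the stellate markers alone, and the matrix and macrophage tests were added after that outcome was seen. The mean rise of the stellate markers exceeded that of the endothelial markers by 0.25 (log2, SE 0.13, 3 mice per group), within 2 SE, so a lower hepatocyte share stays open for them. Matrix genes exceeded the endothelial markers by 0.79 (SE 0.14), which argues against a lower hepatocyte share as the whole cause for matrix genes. For the macrophage markers that rose it stays open. Of the 18 tested macrophage markers, 3 (Cd163, Timd4 and Fcna) were called lower. A lower hepatocyte share alone would raise these as well, so it does not give their falls. The mean rise of the 18 markers exceeded that of the endothelial markers by 0.02 (SE 0.15), within 2 SE. That mean averages rises and falls, so it decides nothing about the markers that rose. Cd163, Timd4 and Fcna did not pass without control 1 (all, adjusted p up to 0.0826), control 2 (all, adjusted p up to 0.105), control 3 (Cd163, adjusted p = 0.0914), knockout 1 (Timd4 and Fcna, adjusted p up to 0.0606) or knockout 2 (Cd163 and Timd4, adjusted p up to 0.0732). Hepatocyte-expressed lists lay lower as well, such as beta-oxidation (relative median -0.32, that of hepatocyte markers -0.44), and a lower hepatocyte share stays open for their falls. A change of the stellate cells or macrophages themselves in the knockouts stays open as untested.

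Scd1 and Fasn rose while Pck1, G6pc and Cyp4a14 fell, as a more fed state of the knockouts at sampling could give. Other fasting-induced genes lay lower as a set (relative median -0.38, 4 of 18 called lower and 1 higher, camera p = 1.36e-05, and p = 0.0321 with an estimated correlation). Other fed-induced genes had a relative median of 0.30, 3 of 14 being called, each higher, with a camera p of 0.98 and a fry p of 0.0417. Feeding state and genotype cannot be told apart for these genes, since the last meal and time of sampling are not given in the sources used here. A direct effect of the knockout stays open as untested.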
